A study of Mus musculus with 4 samples.

How the data were processed

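The study measured total RNA of 3T3-MEFs on 4 biotin-labelled Affymetrix arrays, 2 for wild-type and 2 for SMRTmRID cells, with the genotype and replicate number taken from the sample titles. The deposited table holds 1 intensity per probe set and array on a linear scale, the MAS5 signal per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of a probe set into a signal that is never negative and scales each array. In the deposited intensity values the mean without the lowest and highest 2% of probe sets was 200.0 on every array, so the arrays had already been brought to one level. Detection calls were not used here. Low signals are therefore reported as signals and not as absent, and differences from a low level depend on the pseudocount.

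The table has 45101 probe sets, of which 64 control probe sets were left out. Genes were named from the platform's annotation as recorded by GEO: 34945 of the other 45037 probe sets had 1 gene symbol, 932 had several and were not named, and 9160 were given none here. Gene IDs of 34741 of the named probe sets were found in a table of the assembly GRCm38.p6, which was used for names, for chromosomes and for the positions of neighbouring genes. Each of 18193 genes was represented by its probe set with the highest mean signal. Of 5356 genes with several probe sets above the filter, 66 had probe sets that differed in direction by more than 0.5 (log2) each way. Genes were tested when their mean signal over the 4 arrays exceeded the median of all values, 35.1, which left 11057 genes. The median log2 difference of all tested genes was -0.05. Some genes of the lists had no probe set named here and are not reported, among them the gene of the mutated corepressor.

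Signals were transformed to log2(signal + 16) without further normalization. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, on all 4 arrays, without covariates), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are limma's moderated ones. All p-values in the text are two-sided. A test used values simulated for the 11057 genes of this comparison, with the spread of the real arrays and 200 changed genes. It recovered 58.2% of the 67 genes changed 1.5-fold, 85.1% of the 67 changed 2-fold and 98.5% of the 66 changed 4-fold. Of its calls, 2.42% were unchanged genes. In the data 65.2% of the genes passed, a far larger share than was simulated, so these rates do not carry over directly.

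Gene lists were fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives other than the one without chromosome 7. They comprised 35 lists with 777 symbols, of which 714 had a named probe set and 546 were tested. Each list was tested against all other genes with limma's camera with a preset correlation of 0.01 between its genes, adjusted over the 35 lists. With a correlation estimated from the residuals none of the 7 lists that passed still did. With 4 arrays that estimate rests on few residual degrees of freedom, and how large a shift could pass was not tested. Before adjustment its lowest p was 0.0305 (camera), for unfolded protein and amino acid stress genes. The adjustment gave all 7 the same adjusted p of 0.571 (camera). Counts adjusted over the list alone are given where they differ. Each list's median was also set against 10000 random lists of the same size matched on mean expression. The genes named are the 12 with the greatest rise and the 12 with the greatest fall among those past the threshold with no overlap between the arrays of the genotypes and whose brighter genotype lay above the 60th percentile of signal (64.7) on both arrays, leaving out gene models without a proper symbol, then up to 4 called members of each list with the greatest change, a fixed set of adipogenic genes and the sex-linked genes; other members of lists are named to describe a list and were chosen after their values were seen.

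The replicate numbers name arrays and do not pair them: the deviations of same-numbered arrays from their genotype means correlated at 0.012 across genes. Alternatives were other pseudocounts (1 and 64), other filters, quantile normalization, median centring, no variance trend, other rules for a gene's probe set, the replicate number as a block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9. Gene positions served only to order genes along chromosomes and to count neighbouring genes, and no coordinates are given.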

Results

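Total RNA from undifferentiated fibroblast lines was measured on 4 single-colour Affymetrix arrays, 2 from wild-type cells and 2 from cells carrying SMRTmRID. The cells were 3T3-MEFs, mouse embryonic fibroblasts carried through serial passage until they grow as a permanent line, and they were harvested at confluence before any adipogenic stimulus. SMRT is a corepressor that nuclear receptors recruit to silence their target genes, and the mRID form is altered in the domains through which receptors bind it. The design asks how the transcriptome of such cells differs from that of wild-type cells before differentiation. The mutation changes the corepressor protein, and its own transcript was not analysed here, so the genotype label was not checked here. The labels call the 2 arrays of each genotype technical replicates, without naming the step that was repeated, so every p-value below rests on the spread between technical replicates. How far independent cell lines, embryos or cultures of a genotype vary was not analysed here. With 2 arrays per genotype, the number of arrays limits the precision.

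The arrays of a genotype were close to each other. Across the 11057 tested genes, Pearson's r was 0.991 between the 2 wild-type arrays and 0.991 between the 2 SMRTmRID arrays, and between 0.860 and 0.861 for the 4 pairings of a wild-type with a SMRTmRID array. The median absolute log2 difference was 0.0983 between the wild-type arrays, 0.0987 between the SMRTmRID arrays and 0.43 between the genotypes. The difference of the first pair of arrays and that of the second correlated across genes at r = 0.936, and 86.9% of the genes had the same sign in both pairs. Genes are not independent replicates, so no p-value is attached to these correlations. The ratio of the 3′ to the 5′ beta-actin control probe set, a measure of RNA integrity, lay between 1.19 and 1.20 on all 4 arrays. Control probe sets for pyruvate carboxylase were less even. Their mean 3′ and 5′ signals were 147 and 124 in wild-type and 351 and 183 in SMRTmRID.

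SMRTmRID cells differed from wild-type cells in most of the genes above the filter on signal. Of 11057 such genes, 3346 were higher and 3867 lower in SMRTmRID, together 65.2% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). Without the filter, 6839 of 18193 genes passed. Among the 7213 genes above the filter that passed, 1071 were at least 2-fold higher and 751 at least 2-fold lower, and 74 were at least 10-fold higher and 37 at least 10-fold lower. The arrays of the genotypes did not overlap for 81.5% of the genes, against 33.3% that chance alone gives for 2 arrays against 2. Differences are given as SMRTmRID minus wild-type on the log2(signal + 16) scale, which understates changes from a low level, and signals are means ± SD over 2 arrays.

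Several genes that encode secreted or matrix proteins were among the 12 with the greatest rises, a group that was not tested as such. Ptn, the growth factor pleiotrophin, had a signal of 18.1 ± 3.29 in wild-type and 6829.9 ± 339 in SMRTmRID, a log2 difference of 7.65 ± 0.09 (SE). Lpl, the lipase that releases fatty acids from lipoproteins, went from 9.25 ± 7.69 to 4924 ± 27.8, a log2 difference of 7.65 ± 0.17 (SE). The matrix genes Dcn (decorin), Postn (periostin) and Thbs2 (a thrombospondin) rose by 6.82, 6.78 and 5.32 on the log2 scale, Igfbp3 by 7.04 and the fibroblast surface glycoprotein Thy1 by 6.80. Ms4a4d went from 1.41 ± 0.531 to 2221 ± 226. The neurotensin precursor gene Nts, the hormone gene Stc1, Brinp3 and Gpm6b completed the 12 genes with the greatest rises, with log2 differences of 6.40, 6.02, 5.80 and 5.39. In the other direction, Igfbp2, which encodes another binding protein of insulin-like growth factors, fell from 6475 ± 67.3 to 31.1 ± 0.679, a log2 difference of -7.11 ± 0.07 (SE). Anxa8 had a log2 difference of -6.02, the cartilage collagen gene Col2a1 of -5.64, the prostacyclin synthase gene Ptgis of -5.43, and the complement regulator gene C4bp of -5.26. The transcription factor genes Foxd1 and Lhx9 had log2 differences of -5.15 and -4.39, Perp, a desmosome-associated p53 target, of -5.10, and the desmosomal gene Pkp1 of -4.39. Serpinb6b, Stmn2 and Plac8 had log2 differences of -4.77, -4.69 and -4.32. The adjusted p-values of these 24 genes were at most 1.11e-07 (limma).

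**Figure D1:**
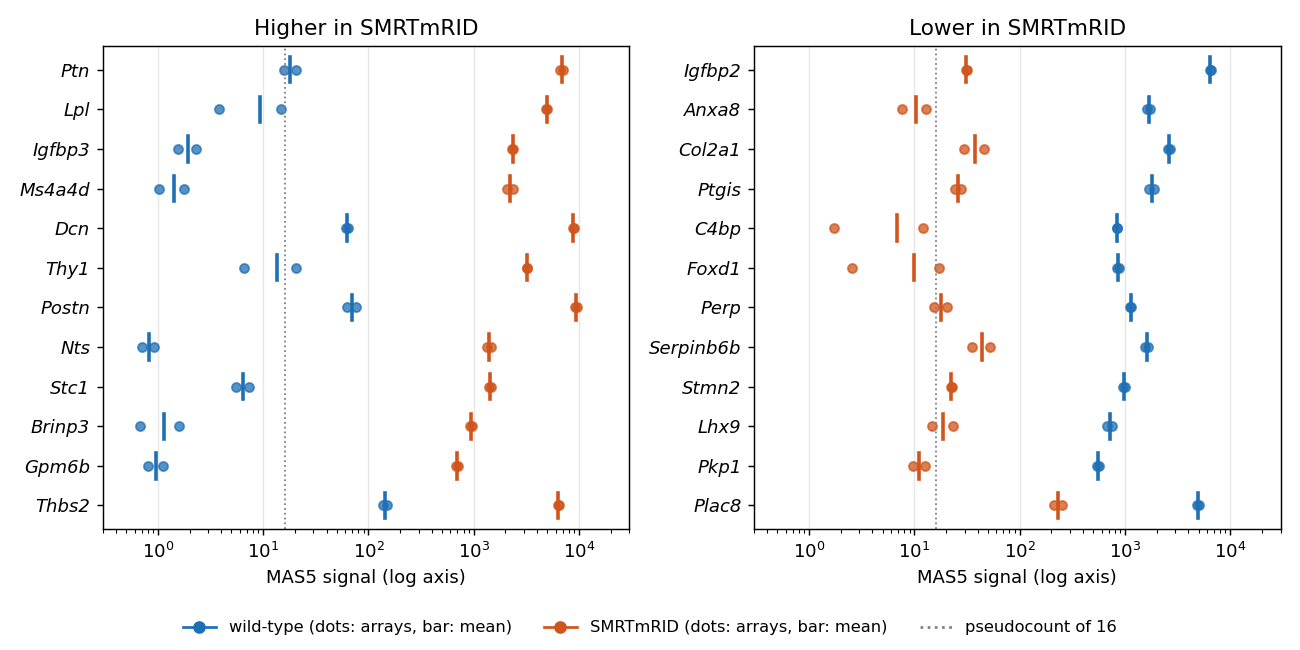
MAS5 signal (log axis) of the 12 genes with the greatest rise and the 12 with the greatest fall in SMRTmRID, with a dot for each of the 2 arrays of a genotype, a bar for their mean and a dotted line at the pseudocount of 16. The arrays of the genotypes do not overlap for any of the 24 genes, and most of the dimmer values lie near or below the pseudocount.

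Adipocyte genes and targets of PPARgamma, the receptor that drives adipocyte differentiation, went both ways, with the greatest changes upward. Of 17 tested members, 8 rose, 5 fell and 4 did not pass the test, and the counts were the same when adjusted over the list alone. Besides Lpl, the detoxifying enzyme gene Mgst1 rose from 201 ± 4.02 to 5782 ± 255, the lipase inhibitor gene Angptl4 from 155 ± 0.492 to 2810 ± 157, and the fatty-acid binding protein gene Fabp4 from 204 ± 9.77 to 1368 ± 57.0, a log2 difference of 2.65 ± 0.07 (SE, adjusted p = 3.69e-09 by limma). Fasn, the fatty acid synthase gene, had a log2 difference of -0.77 and Cd24a of -1.17. The list as a whole did not pass the list test (camera, adjusted p = 0.204), with a median log2 difference of 0.36. Adipoq, the adiponectin gene of mature adipocytes, had signals of 1.92 and 9.54 in wild-type and 15.3 and 13.0 in SMRTmRID and was not tested.

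Of 15 early adipogenic regulators, 7 rose, 5 fell and 3 did not pass the test, or 7 and 7 adjusted over the list alone. Ebf1, a transcription factor gene of adipocyte commitment, rose by 2.51 and Xdh by 2.47, while the Kruppel-like factor genes Klf4 and Klf5 had log2 differences of -2.45 and -1.91. Pparg itself had a signal of 72.1 ± 19.4 in wild-type and 122 ± 1.04 in SMRTmRID (log2 difference 0.66 ± 0.19 SE, adjusted p = 0.0124 by limma). Without wild-type replicate 2 the difference was 0.44 and did not pass (adjusted p = 0.0740). Cebpa rose by 0.62, Cebpd by 0.69 and Cebpb by 0.15, and Cebpb did not pass without wild-type replicate 2 (adjusted p = 0.244) or SMRTmRID replicate 1 (adjusted p = 0.168). Nor did it without a filter (0.101), without a variance trend (0.182) or with the mean of a gene's probe sets (0.0548). The list median was -0.22 and its mean 0.03, and the list test gave the upward direction without passing (camera, adjusted p = 0.895). Inhibitors of adipogenesis and preadipocyte markers also split, with 7 of 19 higher and 10 lower. Wnt10a, a Wnt ligand gene, had a log2 difference of -3.81 and Dlk1, which encodes the preadipocyte factor Pref-1, fell from 1055 ± 169 to 518 ± 0.908, whereas Thy1, Pdgfra and Pdgfrb rose by 6.80, 4.20 and 1.78. This list had a mean of 0.22 and a median of -0.39, and its test pointed down (adjusted p = 0.991).

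Nuclear receptor genes were split as well. Of 20 tested, 11 rose, 8 fell and 1 did not pass. The vitamin D receptor gene Vdr rose from 125 ± 0.875 to 962 ± 72.6, Rora by 2.55, the glucocorticoid receptor gene Nr3c1 by 1.26 and Nr4a2 by 1.23. The retinoic acid receptor genes Rara and Rarg had log2 differences of -0.59 and -0.43, and Rarb had signals between 0.753 and 33.5 and was not tested. The list test gave adjusted p = 0.336. Among 9 receptor coactivator genes 6 rose and 1 fell, led by Nrip1 at 1.55, with adjusted p = 0.267 for the list. Of 4 tested genes of the SMRT complex, Tbl1x and Tbl1xr1 rose by 0.82 and 0.50, and Hdac3 and Gps2 had log2 differences of 0.11 and -0.21 that did not pass (list adjusted p = 0.332).

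Target genes of individual receptors were examined next. Of 14 liver X receptor targets, 8 rose and 3 fell. The cholesterol exporter genes Abca1 and Abcg1 rose by 2.66 and 1.85, Apoc1 by 1.30 and Lpl, which is also on the adipocyte list, by 7.65, while Srebf1 and Fasn had log2 differences of -0.55 and -0.77. The list did not pass (adjusted p = 0.152). It did without wild-type replicate 2 (adjusted p = 0.0313), the lowest of 16 alternatives, of which the highest was 0.677. Retinoic acid receptor targets were even, with 5 of 11 higher, among them Rarres2 at 2.71 and Rarres1 at 2.27, and 5 lower, among them Meis2 at -1.42 and the retinoic acid hydroxylase gene Cyp26b1 at -1.35 (list adjusted p = 0.991, direction down although mean and median were 0.25 and 0.05). Of 8 thyroid hormone receptor targets 2 rose, Klf9 by 1.44 and Me1 by 0.26, and 2 fell (list adjusted p = 0.747). Of 9 vitamin D and glucocorticoid receptor targets 2 rose and 5 fell, with Sgk1 at -1.69 and Tsc22d3 at -1.25 (list median -0.20, not past the threshold of the list test).

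Genes of the unfolded protein and amino acid stress responses were lower in SMRTmRID. Of 25 tested members 21 fell, 2 rose and 2 did not pass, with a median log2 difference of -0.70. Trib3, a stress-induced pseudokinase gene, fell from 1188 ± 62.6 to 392 ± 10.3 and the serine synthesis gene Phgdh from 6611 ± 470 to 2785 ± 107. Sesn2 and the mitochondrial enzyme gene Shmt2 had log2 differences of -1.23 and -1.18, and the chaperone genes Hspa5 and Calr of -0.36 and -0.30, whereas Hsp90b1 and Canx rose by 0.16 and 0.11. The list passed the test (camera, adjusted p = 1.80e-05), but not with a correlation between its genes estimated from the data, which gave adjusted p = 0.571.

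Inflammatory genes were higher. Of 22 tested targets of NF-kB and AP-1, 15 rose, 4 fell and 3 did not pass, with a median of 0.93. The acute-phase genes Saa3 and Hp rose from 479 ± 39.7 to 15372 ± 1152 and from 271 ± 1.12 to 5332 ± 280, the neutrophil chemokine gene Cxcl5 from 344 ± 134 to 5392 ± 87.2 and the cytokine gene Il6 from 125 ± 6.10 to 1749 ± 173. Cxcl1 was close to equal at 10389 ± 38.5 and 10631 ± 543, and Lif, Jun, Ptgs2 and Fosl1 had log2 differences of -0.92, -0.64, -0.34 and -0.27. The list passed (adjusted p = 0.00120), but not with an estimated correlation (0.571). Of 20 interferon-stimulated genes 10 rose and 4 fell, with Gbp2 at 2.10 and Ifit3 at -1.60 (list adjusted p = 0.267). Xaf1, of the same list, rose by 2.54 on its brightest probe set, and its probe sets disagreed in direction.

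Most targets of p53, a transcription factor that responds to DNA damage, were lower. Of 22 tested p53 targets and senescence genes 15 fell, 5 rose and 2 did not pass, with a median of -0.99. Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 2349 ± 34.4 to 155 ± 22.3. Perp, Aen and Phlda3 had log2 differences of -5.10, -2.31 and -2.27, Ccng1 of -1.59 and Mdm2 of -0.40. The members that rose were Sesn1 and 4 cell cycle inhibitor genes that are not direct p53 targets, namely Cdkn1b, Rb1, Cdkn2b and Cdkn2a. Cdkn2a went from 137 ± 31.9 to 647 ± 33.5. Another cell cycle inhibitor gene, Cdkn1c, was among those that fell, with a log2 difference of -1.08. Trp53 itself and Bax were on the list but not among the 22 tested. The list passed at adjusted p = 0.00783, but not with an estimated correlation (0.571).

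Most proliferation genes were lower too. Of 37 tested, 24 fell, 7 rose and 6 did not pass, with a median of -0.43. Mcm5, a subunit of the replicative helicase, fell from 2760.3 ± 26.9 to 897 ± 118. The nucleotide reductase gene Rrm2 had a log2 difference of -1.56 and the mitotic genes Plk1 and Birc5 of -1.35 each, while Mki67 and Top2a rose by 0.64 and 0.25. This list, too, passed at adjusted p = 0.00551 and not with an estimated correlation (0.571).

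Hox genes, which mark position along the body axis, changed in both directions. Of 20 tested 13 rose, each at least 2-fold, 5 fell and 2 did not pass. Hoxd8 went from 7.02 ± 3.18 to 465 ± 11.8, Hoxb6 from 2.12 ± 0.365 to 269 ± 17.6, Hoxb2 from 3.05 ± 2.67 to 255 ± 1.65 and Hoxc8 from 259 ± 28.3 to 2145 ± 104. The members that fell were Hoxa9, Hoxa10, Hoxa11, Hoxc9 and Hoxc10, with log2 differences of -1.08, -0.86, -0.60, -0.47 and -1.10. The list passed in the upward direction (adjusted p = 0.0177), but not with an estimated correlation (0.571). It did not pass without SMRTmRID replicate 1 (adjusted p = 0.1035) or replicate 2 (adjusted p = 0.127), without the filter on signal (0.174) or with genes above the 75th percentile of signal alone (0.859), and its lowest adjusted p over 16 alternatives was 0.00955.

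**Figure D2:**
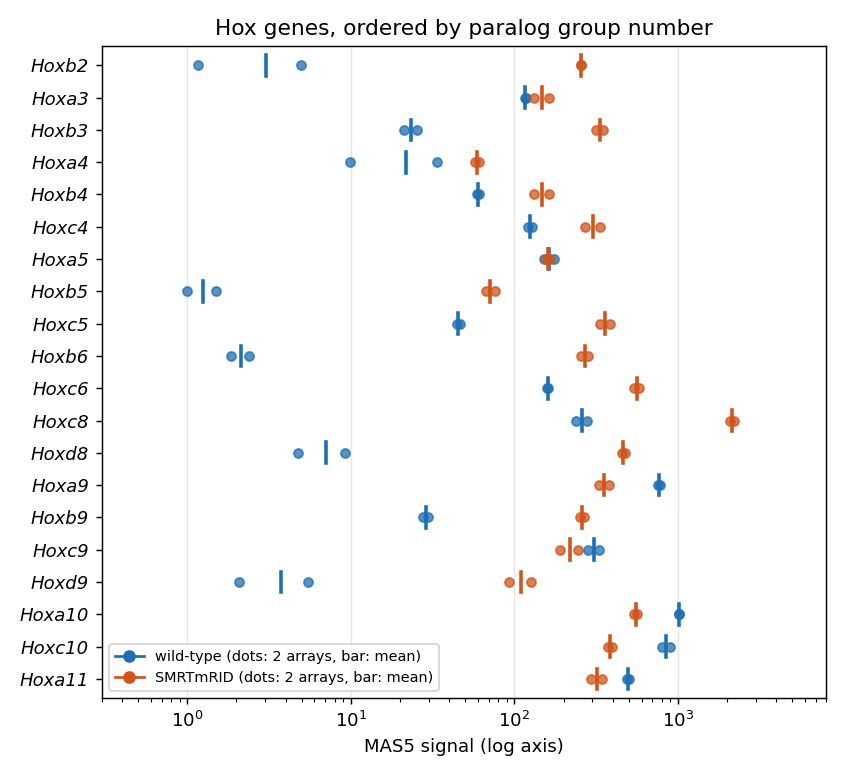
MAS5 signal (log axis) of the 20 tested Hox genes, ordered by paralog group number, with a dot for each of the 2 arrays of a genotype and a bar for their mean. Of the genes with numbers 2 to 8 none was lower in SMRTmRID past the threshold, whereas 5 of the genes with numbers 9 to 11 were and 2, Hoxb9 and Hoxd9, were higher.

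Cholesterol synthesis genes were higher. Of 18 tested, 12 rose and none fell, or 13 and 0 adjusted over the list alone, with a median of 0.36. Sc5d and Idi1, enzymes of the pathway, rose by 1.25 and 1.21, Insig1, a regulator of it, by 0.92 and Hmgcs1 by 0.50. The list passed (adjusted p = 0.00190), but not with an estimated correlation (0.571). Hypoxia and glycolysis genes passed more narrowly (adjusted p = 0.0466), and not with an estimated correlation (0.571). Of 22 tested, 11 rose and 4 fell, with a median of 0.29. Adm and Bnip3, both induced by low oxygen and both on chromosome 7, rose by 2.10 and 1.51. Egln3 and Pdk1 rose by 1.43 and 1.41, while Ndrg1 had a log2 difference of -0.89. That call was lost with genes above the 75th percentile of signal (adjusted p = 0.0516), without a variance trend (0.149), without wild-type replicate 1 (0.0770) and without genes of chromosome 7 (0.233). The lowest adjusted p over 16 alternatives was 0.00504.

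**Figure D3:**
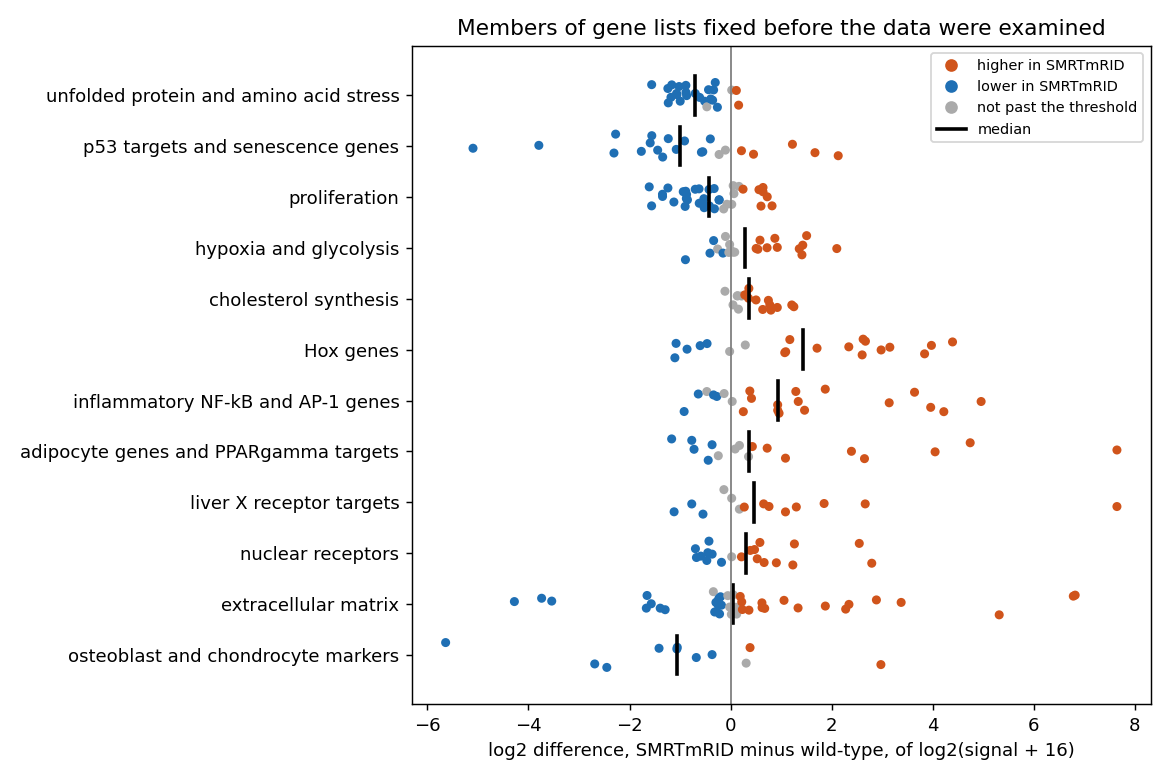
Log2 difference (SMRTmRID minus wild-type, of log2(signal + 16)) of each tested member of 12 of the gene lists, coloured by whether it passed the test, with a black bar at each list's median. The stress and p53 lists have medians of -0.70 and -0.99, the Hox and inflammatory lists of 1.44 and 0.93, and the matrix list spreads widely on both sides of a median of 0.04.

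Matrix genes went both ways. Of 41 extracellular matrix genes 17 rose, 16 fell and 8 did not pass (list adjusted p = 0.553). Besides Dcn, Postn and Thbs2, the proteoglycan gene Vcan rose by 2.89, whereas Efemp1, Col11a1 and the calcification inhibitor gene Mgp had log2 differences of -4.28, -3.74 and -3.54. The abundant fibrillar collagen gene Col1a1 had signals of 13062 ± 504 and 13208 ± 732, a log2 difference of 0.02 ± 0.05 (SE, adjusted p = 0.815). Of 18 matrix protease and inhibitor genes 9 rose, with the matrix metalloproteinase genes Mmp3 at 4.78 and Mmp13 at 4.40, and 6 fell, with Timp3 at -2.77 (list adjusted p = 0.267). Of 14 myofibroblast and smooth muscle markers 5 rose and 8 fell, with Cnn1 at 1.45 and Smtn at -2.16 (list adjusted p = 0.332).

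Markers of other lineages were measured to describe the cells. Of 11 osteoblast and chondrocyte markers 8 fell and 2 rose. Col2a1 went from 2629 ± 104 to 37.7 ± 11.9, Col10a1 and Sox6 had log2 differences of -2.69 and -2.45, and Alpl, the alkaline phosphatase gene, rose by 2.98 (list adjusted p = 0.238). Of 7 skeletal muscle markers 1 rose, Pax3 by 2.44, and 3 fell, led by Acta1 at -3.61 (adjusted p = 0.815), or 1 and 2 adjusted over the list alone. Of 6 neural crest and glial markers 1 rose and 3 fell, with Nes at -2.09 (adjusted p = 0.608). Of 4 epithelial and endothelial markers Krt19 rose by 1.95, and Epcam and the mesothelial gene Msln had log2 differences of -0.37 and -4.08 (list adjusted p = 0.761). Epcam did not pass without wild-type replicate 1 (adjusted p = 0.122) or SMRTmRID replicate 2 (0.0804), without a filter (0.0548) or with the mean of a gene's probe sets (0.253). Of 5 blood cell markers 3 rose, with Lyz2 at 1.65 (list adjusted p = 0.312).

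The remaining lists did not pass the test. In TGF-beta and BMP signalling 11 of 28 genes rose, with Tgfbr3 at 2.39 and Bmpr2 at 2.09, and 15 fell, with Tgfb3 at -1.49 (adjusted p = 0.893, direction down, mean 0.11, median -0.27). In Wnt signalling 10 of 26 rose, with the secreted inhibitor genes Sfrp1 at 5.06 and Sfrp2 at 3.51, and 8 fell, with Dkk3 at -2.24 (adjusted p = 0.539), or 11 and 8 adjusted over the list alone. In Notch signalling 4 of 12 rose, with Notch3 at 2.08, and 3 fell (adjusted p = 0.543). In insulin and IGF signalling 9 of 20 rose and 9 fell, with Igf2 at 3.12 and Igfbp5 at 3.78 beside Igfbp3 and Igfbp2 (adjusted p = 0.893). Of 13 imprinted genes 6 rose, with Peg3 at 2.26, and 6 fell (adjusted p = 0.747). Of 20 NRF2 and antioxidant genes 7 rose, with Gstm2 at 2.85, and 11 fell, with Nqo1 at -2.08 (adjusted p = 0.747, direction down, mean 0.04, median -0.30). Of 18 fatty acid oxidation and mitochondrial genes 6 rose, with Pdk4 at 1.21, and 5 fell (adjusted p = 0.747). Of 15 circadian clock genes 3 rose, with Hlf at 2.63, and 3 fell (adjusted p = 0.792), or 3 and 2 adjusted over the list alone. Of 5 sex-linked genes above the filter 3 rose (adjusted p = 0.267), among them Xist by 0.28 and Kdm6a by 0.61, neither of which passed with the mean of a gene's probe sets (adjusted p = 0.128 and 0.0635).

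Each list's median was also set against 10000 random lists matched on mean expression, a comparison that takes no account of correlation between the genes of a list. Of the 7 lists that passed the list test, those of p53 targets, stress and proliferation genes lay at percentiles 0, 0.01 and 0.09. Cholesterol synthesis and hypoxia genes lay at 98.35 and 99.65, and inflammatory and Hox genes at 100. Among the lists that did not pass, osteoblast and chondrocyte markers lay at percentile 0.01 with a median of -1.05. The joint list of inhibitors of adipogenesis and preadipocyte markers lay at 2.23, with a median of -0.39 but a mean of 0.22. Adipocyte genes lay at 98.32, liver X receptor targets at 98.98, and matrix proteases and inhibitors at 99.4. Unlike the list test, these percentiles were not adjusted over the 35 lists, of which a few can lie this far out by chance. The other lists lay between 3.13 and 96.84.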

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

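The tests of this part were chosen after the data had been seen. The arrays carry 4 control probe sets for pyruvate carboxylase, an endogenous enzyme that feeds carbon into the citric acid cycle and lipid synthesis, which the comparisons above leave out. Their signal was higher in SMRTmRID than in the wild-type controls, with a mean log2 difference of 0.985 and differences of 1.18, 0.51, 1.08 and 1.17 for the 3′, 5′ and both middle probe sets. The gene's own probe set, Pcx, went from 206 ± 21.4 to 497 ± 35.2, a log2 difference of 1.21 ± 0.10 (SE, adjusted p = 4.51e-06 by limma). Probe sets that were given no gene here also held differences. Of 1850 such probe sets above the filter, 239 were at least 2-fold higher in SMRTmRID and 72 at least 2-fold lower. Of all 22481 probe sets above the filter, with or without a gene, 2426 and 1270 were. Whether these shares differ was not tested.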

How the results depend on the processing

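The counts of genes higher and lower in SMRTmRID stayed within 1.5 times of 3346 and 3867 when genes were tested under the other settings; between 6287 and 6378 of the 7213 calls kept their direction and their call when 1 array was left out, and 45 turned to the opposite call with the mean of all probe sets of a gene. Testing every probe set on its own, which tests 22481 probe sets, gave 7017 higher and 6348 lower, and 2426 and 1270 at least 2-fold. The counts at least 2-fold higher and lower were 687 and 500 with a pseudocount of 64, which shrinks differences of dim genes, and 577 and 451 with genes above the 75th percentile of signal, of which fewer are tested. The correlation of the pair differences, 0.936, was 0.914 with a pseudocount of 1, 0.954 with 64, 0.790 without a filter, 0.977 above the 75th percentile and 0.932 with the mean of all probe sets. The number of lists past the threshold, 7, was 0 with an estimated correlation and between 6 and 8 with 1 array left out, where the lone array is assumed to vary like the others. Leaving out 1 array gave between 1009 and 1148 genes at least 2-fold higher and between 714 and 814 at least 2-fold lower. With the replicate number as a block, a pairing that the labels do not give, the counts were 3433 higher and 3987 lower with 7 lists, and 7170 of the 7213 calls held. Quantile normalization gave 3111 higher and 4201 lower, 42.5% higher against 46.4%. Without genes of chromosome 7, chosen after seeing the data, 6 lists passed and hypoxia and glycolysis did not (camera, adjusted p = 0.233). Adm and Bnip3, the members of that list with the greatest rises, lie on chromosome 7 and were left out with it. Rfng of the Notch list, higher by 0.50, was at -0.19 without SMRTmRID replicate 2 (adjusted p = 0.244) and at 0.07 without SMRTmRID replicate 1 (adjusted p = 0.641), because another of its probe sets was then the brightest; with the probe set kept it was at 0.41 and 0.58. Without one or the other wild-type array it was between 0.40 and 0.60. Leaving out 1 array changed the brightest probe set of between 120 and 159 of the tested genes. Of the named genes under all alternatives, 2195 values kept their direction and side of the threshold, 38 lost the call, 3 gained it and 1 reversed. Arrays without detection calls limit what can be said of dim genes.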

Other observations

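The tests of array scaling, copy number, cycling cells, genotype against cell line, axial position and retinoic acid receptor targets were chosen after the result was seen. The genes of this paragraph were chosen after their values were seen, and 65.2% of all tested genes passed the threshold, so they do not show that developmental transcription factors differ more than other genes. Shox2, a limb patterning factor, went from 28.7 ± 2.69 in wild-type to 1513 ± 3.95 in SMRTmRID, Zic1 from 5.76 ± 6.07 to 638 ± 13.8 and Irx1 from 13.5 ± 2.89 to 556 ± 77.4. In the other direction Pax8 went from 522 ± 52.6 to 35.9 ± 5.05, Gsc from 295 ± 7.32 to 8.52 ± 5.35 and Lmo1 from 256 ± 45.4 to 6.90 ± 8.16. The growth factor gene Hgf rose by 4.80 on the log2 scale, and Cdsn, which encodes a protein of cornified epithelium, had a log2 difference of -4.22.

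In both genotypes Xist was well above the filter on signal and the Y-linked genes measured were below it. Xist, the RNA of the inactive X chromosome, had signals of 1086 ± 41.2 in wild-type and 1322 ± 55.3 in SMRTmRID, a log2 difference of 0.28 that passed the threshold (adjusted p = 0.00179 by limma). The probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty had signals of at most 24.8 on all 4 arrays, below the filter of 35.1.

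Genes of chromosome 7 were lower in SMRTmRID as a group. Of its 814 tested genes 77.6% had a negative difference, with a median of -0.54, and 500 were called lower against 76 higher. The median minus that of the other chromosomes was -0.529 (95% bootstrap interval from -0.592 to -0.485). That interval comes from resampling genes, which are not independent replicates. It does not measure how cell lines or chromosomes vary. Array scaling that depends on signal was argued against, since the difference was -0.551 after quantile normalization between arrays. Gene density was too, since the difference from 1000 draws of genes in equally gene-dense neighbourhoods was -0.437, as were dim probe sets, since it was -0.631 among the brightest tested genes, 196 of them on chromosome 7. A chromosome copy number that differs between the cells of the genotypes stays open, and 100% of the 20 consecutive blocks of 40 genes had a median below that of the other chromosomes. With 77.6% of the genes negative, blocks of these genes in any order would mostly lie below that median. The block count therefore cannot tell a copy number from a shift of genes scattered along the chromosome. Long runs in one direction were not particular to chromosome 7, since 14 of 15 blocks on chromosome 8, 8 of 9 on chromosome 12 and 13 of 15 on chromosome 1 lay below that median and 0 of 7 on chromosome 18. The block medians of chromosome 7 lay between -0.76 and -0.23, and those of chromosome 8 between -0.54 and 0.22. Smaller shifts were seen on chromosomes 8 (median -0.29), 18 (0.36) and X (0.35), and without genes of chromosome 7 the genes at least 2-fold lower numbered 584. DNA was not analysed here, and an effect of the genotype on these genes stays open as untested.

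The fall of p53 targets has more than one open reading. Most of the proliferation list argued against more cycling cells in SMRTmRID, with a median of -0.426, 24 of 37 genes lower and 7 higher. The members had an SD of 0.666, and the 7 included Mki67 and Top2a, at 0.64 and 0.25, so the list was not uniform. Its list test passed with the preset correlation (adjusted p = 0.00551) and not with an estimated one (0.571), as did that of the p53 list. Lower p53 activity in the SMRTmRID cells may be a candidate explanation: on a second list that shared no gene with the first, 23 of 45 tested genes fell and 9 rose, with a median of -0.31 that lay at the 0.78th percentile of random lists matched on signal. Among all 11057 tested genes 3867 fell and 3346 rose. The percentile takes no account of correlation between the genes of a list, and the list test was not run on the second list. The members of the second list with the lowest values were Crip2, Psrc1 and Ephx1, with log2 differences of -3.09, -2.46 and -2.22. Those with the highest values were Pitpnc1, Fas and Polk, with log2 differences of 0.91, 0.82 and 0.74, all past the threshold. Permanent fibroblast lines often lose part of the p53 pathway during establishment, which is background and was not tested. Genotype and a chance difference between 2 cell lines cannot be told apart here, because the 2 arrays of each genotype are technical replicates.

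The calls of Hox genes did not depend on probe sets of the _s_at and _x_at kinds, since 19 Hox genes passed the threshold on other probe sets. Several Hox genes, among them Hoxd8 and Hoxb6, were already represented by other kinds. Cross-hybridisation of those probe sets between paralogs was not tested. Cells from different positions along the body axis remain a possible explanation: the difference fell with the paralog group number across 20 genes, but the correlation did not pass (Spearman's rho = -0.405, permutation p = 0.0784; Pearson's r = -0.394, permutation p = 0.0868, and -0.236 without the 2 genes farthest from the median number; adjusted over both, p = 0.0868 for each). Genes are not independent replicates. Release of retinoic acid receptor targets by the mutation stays open too, since the 11 targets went both ways and their median lay at the 62.4th percentile of random lists. Rarb, below the filter, was not among the 11.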
